A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

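Chromatin immunoprecipitation followed by hybridisation to tiling arrays (ChIP-chip) was carried out in asynchronous wild-type fission yeast, Schizosaccharomyces pombe, grown at 30 C. There were 6 arrays of 5 targets: trimethylated histone H3 lysine 9 (H3K9me3) and the FLAG-tagged Clr4, FLAG-tagged Cul4, Myc-tagged Raf2 and Myc-tagged Rik1 proteins. Rik1 had 2 arrays and each other target had 1. Cells were fixed with paraformaldehyde and dimethyl adipimidate, and both the immunoprecipitated DNA and the whole-cell-extract input were amplified by random-primed PCR before labelling, per the labels' protocols. On every array the immunoprecipitated DNA carried Cy5 (red) and the input carried Cy3 (green), per the labels, so every ratio here is ChIP over input. No dye swap, mock or untagged array was analysed here.

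Samples were grouped by the target in their titles, and replicate numbers were also taken from the titles. For Clr4, Cul4, H3K9me3 and Raf2 the title gives replicate number 1 and the description gives number 2, so the number served only as a name. The series' design text names FLAG antibodies in general, while the titles and descriptions name Myc for Raf2 and Rik1 and the histone mark itself for H3K9me3; the latter were followed.

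The authors deposited, for each array, the spot intensity in both channels as Agilent Feature Extraction wrote it. Version 8.5.1.1 made the 5 arrays of an older 60-base tiling design and version 9.5.1.1 made Rik1 replicate 2, which was hybridised to a newer design with the same probes, per the file headers. The deposited processed intensity had no background subtracted. It was dye-normalised within the array, by LOWESS on the Clr4, H3K9me3, Raf2 and Rik1 replicate 1 arrays and by a rank-consistent linear fit on the Cul4 and Rik1 replicate 2 arrays, per the file headers. The log10 ratio column deposited beside it equalled the ratio of the 2 processed signals and was used only as a check. The authors' deposited value table holds log2 values. Set against the scanner values, it followed the log2 ratio of red over green mean signals, with column medians of 0.01 for Clr4, 0.02 for Cul4, 0.01 for H3K9me3, 0.04 for Raf2, 0.01 for Rik1 replicate 1 and 0.32 for Rik1 replicate 2. Its scale and direction were therefore settled by that match, and the centring step of the first 5 columns is not given in the sources used here. Of the deposited flags, in no unit, the outlier, saturation and above-background flags were used.

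Each array carried 41551 probes that were not controls. Probe sequences were matched exactly, on both strands, to the S. pombe assembly ASM294v3, which names every coordinate below. The build used to design the array is not given in the sources used here, and no coordinate of the probe names was mixed with the assembly. In all, 41449 probes matched, 40396 of them once and 1053 more than once, and 102 did not match. Of the latter, 36 lay in the silent mating-type interval that this assembly does not hold and 62 in a subtelomeric clone. A total of 38 mating-type probes were placed on the array design's own mating-type stretch by the positions in their names. The centromeric outer repeats, the central domain and the cenH element are not annotated in this assembly. The outer repeats were taken as the span of probes with at least 4 matches in each centromere, and the central domain within it as the stretch bounded by tRNA genes. The cenH element was delimited with BLAST+ 2.17.0 as the mating-type probes sharing at least 30 identical bases with the outer repeats.

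The measure was log2 of the processed ChIP over the processed input intensity, centred on each array's median, with control and outlier spots left out and saturated spots kept, so that the strongest ratios, and the centromere means used for scaling, are capped on arrays with saturated ChIP spots. Probes were averaged in bins of 1000 bp with at least 2 probes. A bin was called enriched above the smallest threshold t at which the bins below -t numbered at most 5 percent of the bins above t, with t at least 0.5. Runs of enriched H3K9me3 bins were joined over gaps of at most 2 bins and kept as domains when 3 or more bins were called. Domains were classed as centromere, mating-type (mat) locus, chromosome end (within 100 kb of an end of chromosome I or II), chromosome III end or other. Differences between the median inside and outside the domains were placed among 10000 circular shifts of the domains, and medians of gene lists among 10000 random lists of the same size matched on input signal. These percentiles describe 1 array and are not tests.

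With 1 array per target, no test was made between targets, and classes were compared within an array, also as a percentage of that array's own centromere mean. The only test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) of the 2 Rik1 arrays' binned log2 ratio against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The control is the input on the same array, so the spread of the input between cultures is left out. The labels do not say that the 2 Rik1 arrays came from separate cultures, so the spread between these 2 arrays may be technical. The p-values rest only on that spread, pooled largely over all bins (prior degrees of freedom 56.0). A bin can therefore pass although its 2 arrays differ widely. The number of arrays limits the precision throughout. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

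The median signal over background in the input channel was 3.84 for Clr4, 4.64 for Cul4, 3.94 for H3K9me3, 4.60 for Raf2, 6.34 for Rik1 replicate 1 and 435 for Rik1 replicate 2. After the outlier filter 40676, 38724, 41375, 32039, 40242 and 39367 probes remained on these arrays in that order. The calls were tested on simulated data. Of 15 simulated domains of H3K9me3 placed on 12420 bins, 15 were found at a log2 fold of 2 and at 3 and 0 at a log2 fold of 1, with 0 false domains. The simulated background was drawn bin by bin from bins below the threshold, without the correlation of neighbouring bins. The 0 false domains therefore do not give the rate in the real data. Of 200 simulated Rik1 bins among 12258, limma recovered 0 percent at a log2 fold of 0.5, 71.5 percent at 1 and 100 percent at 2, and the share of false calls was 12.3 percent at 1 and 11.1 percent at 2, above the nominal rate.

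Genes were named by a rule fixed before the data were examined, with at least 2 probes per gene. The rule took up to 4 genes per domain with the highest H3K9me3, the 10 genes with the highest H3K9me3, and the 6 with the highest mean over the 4 subunits at least 5 kb outside the domains. It further took the 5 genes inside domains with the highest and the 5 with the lowest value of subunit mean minus H3K9me3, each array divided by its own centromere mean; of the former only SPAC212.06c had a value above 0. Last came the 3 genes with the largest excess of each single subunit, the Mmi1-target meiotic genes, the telomere-linked helicases and the 4 tagged genes. Genes in repeats, or with input above single-copy level, were treated as uncertain. Gene lists were fixed at the same time: Mmi1-target meiotic genes, other meiotic genes, heterochromatin machinery, highly transcribed genes, mating-type cassettes, telomere-linked helicases, Tf2 retrotransposons, wtf genes, tRNA genes (at least 1 probe) and mitochondrial genes. The genes listed as mcp5 and mug1 are num1 and jnm1 in the assembly.

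The alternatives tried were normexp background correction with an offset of 50, loess within each array, centring on the mode, the authors' deposited table, only probes above background, no saturated probes, bins of 2 kb and of 500 bp, correction for probe GC content, fixed thresholds of 1.5-fold and 2-fold, probes matching once, an intensity trend and a 1.2-fold minimum in limma, the median over probes of a gene, and leaving out either Rik1 array. Keeping outlier spots, using only probes at single-copy input level, using only probes that match once for the domains, the enriched bins and the Rik1 test, all alternatives of the correlation between the Rik1 arrays, these probe filters for the class levels, and for the gene lists loess, the mode, the deposited table and the GC correction were added after seeing the data. Probes without a match in the assembly and off the mating-type stretch were left out of all comparisons. No sequence-level result was sought, since the arrays measure hybridisation only.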

Results

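The binding of the Clr4 methyltransferase complex (ClrC) along the genome of fission yeast labelled wild type was measured on 6 tiling arrays, each comparing immunoprecipitated DNA with whole-cell input. Clr4 is the enzyme that methylates histone H3 at lysine 9, and Rik1, Cul4 and Raf2 are parts of the cullin-based ubiquitin ligase in the same complex. The targets were trimethylated H3 lysine 9 (H3K9me3), Clr4, Cul4 and Raf2 with 1 array each and Rik1 with 2 arrays. Each array carried 41551 probes at a median spacing of 300 bp, and between 32039 probes (Raf2) and 41375 probes (H3K9me3) were used. The median input signal was between 1214 (H3K9me3) and 1919 (Rik1 replicate 1) on the 5 arrays of the older design and 18315 on Rik1 replicate 2. The input of Rik1 replicate 1 was lower over set7, a gene singled out after its values were seen, than on the other older arrays (-2.68 on the log2 scale), so the wild-type label of that array is in doubt. Values are log2 ratios of ChIP over input, centred on each array's median, and coordinates refer to assembly ASM294v3. Saturated spots cap the strongest ratios: in the centromeric outer repeats 65.5 percent of the H3K9me3 probes were saturated, 33.3 percent of Raf2, 24.7 percent of Rik1 replicate 1, 6.74 percent of Clr4 and 0 percent of Cul4 and Rik1 replicate 2. Targets with 1 array have no replicate check, so an SD given for them is the spread over bins or probes.

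The first comparison asked where the heterochromatin mark lay. H3K9me3 formed 15 domains covering 185 kb: 7 at the centromeres (69 kb), 6 at the ends of chromosomes I and II (96 kb) and 2 at the mating-type (mat) locus (20 kb). No domain was called elsewhere or at the ends of chromosome III at the threshold of 1.51. A fixed 2-fold threshold also gave 15 domains and none elsewhere. At lower thresholds, the authors' deposited table (0.5) gave 26 domains with 7 elsewhere and probes at single-copy input level (0.52) 8 with 4 elsewhere. A fixed 1.5-fold threshold gave 18 with 1 elsewhere, 500 bp bins (1.58) 24 with 2 elsewhere, and probes that match once (0.94) 5 in all. The longest chromosome-end domains spanned I 1 to 36000 and I 5546001 to 5579000. The first of these held tlh1, a telomere-linked helicase gene, with a mean H3K9me3 log2 ratio of 3.42, and its neighbours SPAC212.08c (3.61), SPAC212.09C (3.51), SPAC212.07C (3.29) and SPAC212.10 (2.68). The second held SPAC750.08c (3.75), the highest mean of all genes measured, SPAC750.07c (3.52), SPAC750.01 (2.55) and pdc102, a pyruvate decarboxylase gene (2.59). Saturated H3K9me3 probes made up 70.6 percent of the terminal 10 kb on the left and 37.1 percent on the right. The order of the highest genes is therefore not settled.

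On chromosome II, the end domains spanned 1 to 5000, 8001 to 15000, 4497001 to 4507000 and 4535001 to 4539804. The first held SPBC1348.15 (H3K9me3 1.96), the second ftm5 (2.18), SPBC1348.04 (2.11) and SPBC1348.05 (1.96), and the third ftm7 (1.98), SPBPB2B2.18 (2.49), SPBPB2B2.19c (2.10) and SPBCPT2R1.01c (2.09). The last, without annotated genes, averaged 3.49, level with the mat stretch named below, and saturation leaves the order of the highest domain means open. Centromeric domains lay at I 3752001 to 3765000 and 3785001 to 3791000, at II 1602001 to 1610000, 1614001 to 1619000 and 1638001 to 1644000, and at III 1069001 to 1092000 and 1133001 to 1141000. The second ended inside emc5 (I 3790924 to 3791756), an endoplasmic reticulum membrane complex gene that lay mostly outside it and averaged 1.25. The mat domains were II 2129001 to 2137000, which held the silent cassette gene mat3-Mc (2.61), and the 12 kb of the array's own mating-type stretch that is absent from the assembly (mean 3.49). Most chromosome-end genes, tlh1 and SPAC750.08c among them, shared probe sequence with other chromosome ends and are uncertain as single loci, whereas SPAC212.07C, pdc102 and emc5 had only probes that matched once. Of 12415 H3K9me3 bins 183 were enriched, 165 of them inside the domains. The number was 514 in the authors' deposited table, at its lower threshold of 0.5, and 116 without saturated probes.

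The second comparison asked whether the subunits occupied the marked domains. On all 5 subunit arrays the domains stood above the remaining genome. The median inside exceeded the median outside by 1.37 for Clr4, 1.26 for Raf2 and 0.48 for Cul4, against 3.18 for the mark itself. For Rik1 the difference was 0.45 on replicate 1 and 1.93 on replicate 2, with a mean of 1.19 ± 1.05 (SD, n = 2), so the size of the Rik1 signal was not determined beyond the spread between its arrays. The difference of each subunit array lay at percentile 100 of 10000 circular shifts of the domains along the genome. The shifted places were not matched for repeated DNA. Rik1 replicate 2 also read high at other repeated DNA (1.74 at Tf2 elements), so its percentile does not by itself show Rik1 binding. Of the domain bins, 65.5 percent were enriched for Clr4, 65.9 percent for Raf2, 94.6 percent for Rik1 replicate 2, 33.1 percent for Rik1 replicate 1 and 3.01 percent for Cul4. These shares depend on the processing: genome-wide, Raf2 had 107 enriched bins but 3 after loess and 40 with outlier spots kept, Rik1 replicate 2 had 272 but 24 at single-copy input level, and Cul4 had 7 but between 0 (loess) and 541 (centred on the mode). With domains called anew under each alternative, the Cul4 difference was 0.22 after loess and 0.15 in the authors' deposited table. It was 0.14 with probes that match the genome once and 0.0729 without saturated probes. At single-copy input level it was 0.0301, which is close to 0, but over domains that differ from the main ones. In the main domains, probes at single-copy input level gave Cul4 0.67 at the mat locus, 0.42 at centromeres and 0.07 at chromosome ends. No test was made between targets, since each has 1 array apart from Rik1.

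The third comparison set the classes of heterochromatin side by side within each array. Over all probes, Clr4 was 1.72 at centromeres, 1.55 at the mat locus and 0.95 at chromosome ends, and Cul4 0.80, 0.75 and 0.16. In the same order H3K9me3 read 3.19, 3.23 and 2.54 and Raf2 1.30, 1.39 and 0.81, with centromere values capped by saturation on these arrays. As a share of the array's own centromere mean, chromosome ends reached 79.4 percent for H3K9me3, 62.5 percent for Raf2, 55.1 percent for Clr4 and 20.5 percent for Cul4. Rik1 was highest at the centromeres on both arrays, at 2.16 and 2.77 (mean 2.47 ± 0.43, SD, n = 2). At the mat locus Rik1 averaged 1.35 ± 0.84 and at chromosome ends 1.03 ± 1.14 (SD, n = 2), with replicate 1 at 0.76 and 0.22 and replicate 2 at 1.94 and 1.84.

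The order of these classes rests on multi-copy probes. Over the few domain bins built from probes that match once (6 centromeric bins for Clr4), Clr4 was 0.78 at centromeres, 1.42 at the mat locus and 1.21 at chromosome ends. In the same order Raf2 was 0.93, 1.45 and 1.38. At the mat locus these bins also hold probes of the array's own stretch that have no match in the assembly. Centromeres were thus lowest for both, whereas over all probes they were highest for Clr4 and between the other classes for Raf2. Rik1 replicate 1 then read 0.81, 0.44 and 0.50 and kept centromeres highest, whereas Rik1 replicate 2 read 1.70, 1.64 and 1.72 and no longer separated the classes. Cul4 stayed lowest at chromosome ends, at 0.18 against 0.52 at centromeres, but its share of the centromere mean was -7.90 percent after normexp. In the authors' deposited table Clr4 at chromosome ends was 89.5 percent of its centromere mean.

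**Figure D1:**
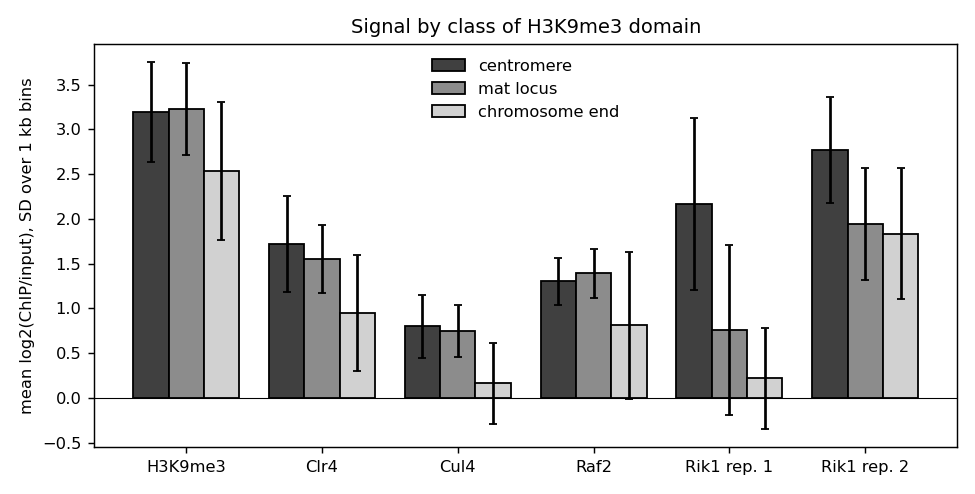
Mean log2 ratio of ChIP over input for each array in the centromere, mat locus and chromosome end classes of H3K9me3 domains; error bars are the SD over 1 kb bins. Rik1 replicate 1 falls from 2.16 at centromeres to 0.22 at chromosome ends, and Rik1 replicate 2 from 2.77 to 1.84.

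The series title names nucleation and spreading, so parts of the domains were compared next. In the centromeric outer repeats, which are transcribed and feed the RNA interference pathway, Clr4 averaged 1.76, Cul4 0.86, Raf2 1.30 and Rik1 2.30 and 2.82 on its 2 arrays. In the central domain, which carries the kinetochore, no array exceeded 0.26. At the mat locus, the cenH element, a stretch related to the outer repeats, carried Rik1 at 2.56 and 3.05, while the remainder between the inverted repeats carried 0.25 and 1.67. For Clr4 these parts had 2.05 and 1.42, for Cul4 1.09 and 0.64, for Raf2 1.37 and 1.37, and for H3K9me3 3.43 and 3.15. The drop from cenH to the remainder was thus larger for Rik1 replicate 1 than for Clr4 or Cul4. H3K9me3 and Raf2, with 90.9 and 50 percent of their cenH probes saturated, cannot be ranked with them, nor can Rik1 replicate 2, whose input read cenH at -0.48 against 1.21 to 2.80 on the other arrays. Beyond the inverted repeats H3K9me3 was 0.36 and Clr4 0.12. Only 1 of the 11 cenH probes passed the filter for probes that match once, and that probe had no match in the assembly. Over outer-repeat probes matching once Clr4 averaged 0.94, so that neither the levels in the outer repeats nor their order against other parts and arrays is settled.

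**Figure D2:**
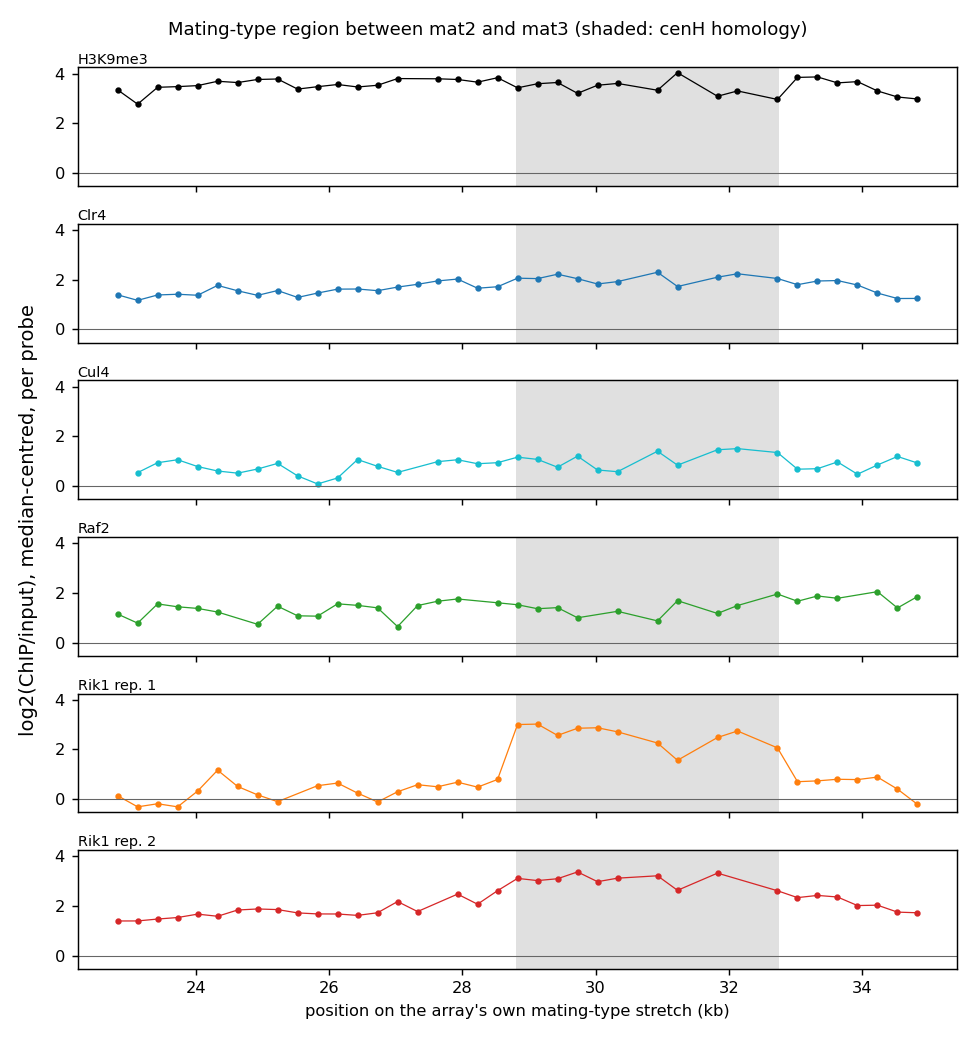
Log2 ratio of ChIP over input per probe on the 6 arrays along the array's own mating-type stretch, in kb, with the cenH homology shaded from 28800 to 32759. H3K9me3, saturated at 90.9 percent of cenH probes, could not show a rise there, and Rik1 replicate 1 averages 2.56 in cenH and 0.39 over the other probes of the stretch.

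The ends of chromosome I differed between subunits. In the terminal 10 kb on the left, H3K9me3 averaged 3.50, Clr4 1.75, Raf2 1.51, Cul4 0.79 and Rik1 replicate 2 2.69, while Rik1 replicate 1 was at 0.07. Between 20 and 30 kb from the same end H3K9me3 was still 1.81, with Clr4 at 0.19, Raf2 at 0.07, Cul4 at -0.12 and Rik1 at -0.07 and 1.53 on its 2 arrays. On the right end at the same distance H3K9me3 was 2.44 with Clr4 at 1.32 and Raf2 at 1.37, but Cul4 at -0.01 and Rik1 at 0.03 and 1.38. Among the ends of chromosomes I and II, the terminal 10 kb of chromosome II on the right had the strongest occupancy, with Clr4 at 1.98, Raf2 at 2.43, Cul4 at 1.02 and Rik1 at 1.72 and 3.59.

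Clr4 and Raf2 continued past the edge of the mark at the right end of chromosome I. From 30 to 40 kb from this end H3K9me3 was 1.03, and from 40 to 50 kb it was 0.17, whereas Clr4 was 1.12 and 0.67 and Raf2 1.09 and 0.48. Cul4 was -0.05 and -0.14 there, Rik1 replicate 1 was 0.14 and -0.00343, and Rik1 replicate 2 was 0.60 and 0.02. Part of the window from 30 to 40 kb lay inside the domain. SPAC186.04c (I 5538480 to 5539519) outside the domain, had Raf2 at 1.30 and Clr4 at 1.04 with H3K9me3 at 0.22. Its neighbour gdt1 (I 5540032 to 5541481) had Raf2 at 1.16, Clr4 at 1.06 and H3K9me3 at 0.52, and SPAC186.06 had 0.95, 1.18 and 0.69. Inside the domain, SPAC186.07c and SPAC186.08c were among the genes with most subunit relative to the mark, with Raf2 at 1.16 and 1.34 and H3K9me3 at 1.62 and 2.21. The probes of these 5 genes matched the genome once.

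**Figure D3:**
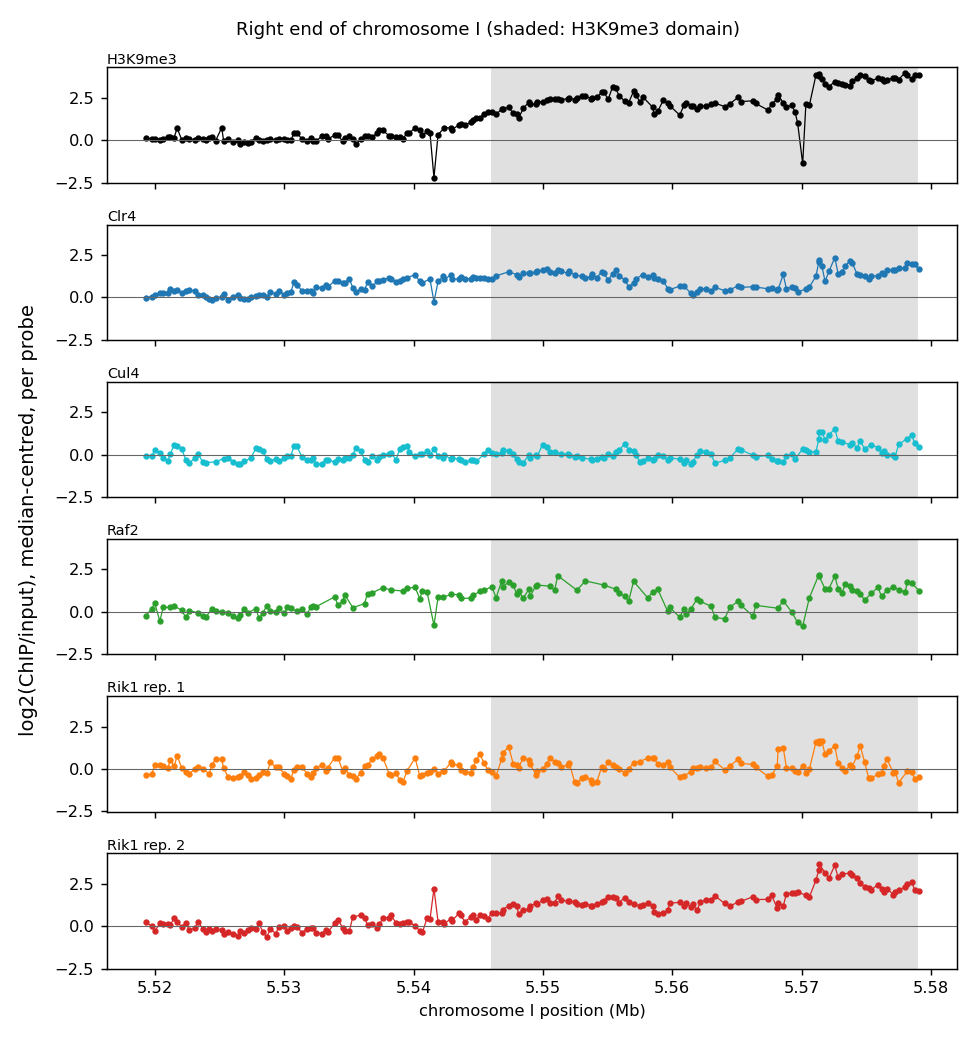
Log2 ratio of ChIP over input per probe on the 6 arrays along the last 60 kb of chromosome I, in Mb, with the H3K9me3 domain shaded from 5546001 to 5579000. Left of the domain, from 40 to 50 kb from the end, Clr4 averages 0.67 and Raf2 0.48 while H3K9me3 averages 0.17.

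Genes with the opposite balance, much mark and little Clr4, Raf2 and Cul4, also lay at chromosome ends, although Rik1 replicate 2 was between 1.19 and 1.40 at 4 of the 5, above its threshold of 1.14. Rik1 replicate 1 lay between -0.34 and 0.14 at these 4. Replicate 2 also read high at other repeated DNA (1.74 at Tf2 elements, 1.33 at wtf genes), so its values at these 4 do not establish Rik1 binding. The remaining gene, SPAC212.07C, had Clr4 at 0.51 and Raf2 at 0.68 beside H3K9me3 at 3.29. SPAC750.02c, SPBC1348.15, SPBC1348.05 and ftm7 had H3K9me3 between 1.96 and 1.98 with Raf2 between -0.26 and 0.06 and Cul4 between -0.41 and -0.07, and their probes recur at several ends. In the same domains, SPAC212.06c was the gene with most subunit relative to the mark, at 2.00 for Clr4, 1.01 for Cul4 and 3.21 for H3K9me3. SPBPB2B2.16c, with SPAC186.06 and the mitochondrial rnl, was among the 3 genes with the largest excess of Clr4 over the other subunits once each array was scaled to its centromere mean, at 0.77 with Raf2 at -0.16.

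The fifth comparison asked whether subunit levels followed the level of the mark, bin by bin. Genome-wide the correlation with H3K9me3 (Pearson r over bins, which are not independent replicates) was 0.71 for Clr4, 0.60 for Raf2, 0.52 and 0.49 for the Rik1 arrays and 0.25 for Cul4. Inside the domains it was 0.81 for Clr4, 0.75 for Raf2, 0.71 for Cul4 and 0.53 and 0.73 for Rik1. Outside the domains it was 0.40 for Clr4, 0.41 for Raf2, 0.10 for Cul4 and 0.50 and 0.00216 for Rik1. The genome-wide values thus also hold variation shared outside the domains, above all for Rik1 replicate 1. Between subunits r inside domains ran from 0.47 (Raf2 with Rik1 replicate 1) to 0.84 (Clr4 with Raf2). The Rik1 arrays correlated at 0.76 inside the domains, at 0.00 outside and at 0.22 genome-wide (0.00940 with probes that match once). Over the 112 bins of mat and chromosome-end domains the Rik1 arrays correlated at 0.55, with a rank correlation of 0.27. Inside domains called anew, their correlation was 0.78 with probes that match once. At single-copy input level it was 0.12, over 8 domains of which 4 lay elsewhere. Over probes matching once, the correlations with H3K9me3 inside domains fell to 0.22 for Clr4, 0.32 for Raf2 and 0.29 for Rik1 replicate 1, and the genome-wide value of Rik1 replicate 2 fell to 0.19, its rank correlation being 0.00853 over all probes.

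The sixth comparison tested Rik1 against its input over 2 arrays with limma. Rik1 was above input in 146 of 12258 bins and below in 2, at an adjusted p under 0.05, and 453 and 238 bins passed without adjustment. Of the 146 bins, 138 were above 0 on both arrays and 116 were also enriched for H3K9me3. The bins above input included 52 of 53 in centromeric domains, 14 of 19 at the mat locus and 43 of 93 at chromosome ends. Outside the domains, 8 of 185 bins at chromosome III ends, 6 of 41 at centromeres and 1 of 265 at the other chromosome ends passed. Of 11602 bins away from all these places 22 passed, most of them in Tf2 retrotransposons and wtf genes. On Rik1 replicate 1 the medians of these gene lists were 0.00 and 0.10. At ura4 the 2 bins had log2 ratios of 2.09 ± 0.23 (SE, limma adjusted p = 2.37e-10) and 1.45 ± 0.24 (SE, limma adjusted p = 1.36e-05), and a bin at mae1, a malate transporter gene, reached 1.76 ± 0.24 (SE, limma adjusted p = 1.17e-07). The 2 bins below input lay in tdh1, a glyceraldehyde-3-phosphate dehydrogenase gene (-1.05, limma adjusted p = 0.00244), and ppc89, a spindle pole body gene (-0.83, limma adjusted p = 0.0492), both named after their values were seen. The number of bins above input was 76 when arrays were centred on the mode and 22 with only probes at single-copy input level. Either array alone gave 84 (replicate 1) and 272 (replicate 2) enriched bins, called by its own threshold and not by limma.

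Outside the domains, ura4 (III 115589 to 116625), which encodes orotidine monophosphate decarboxylase and is widely used as a selectable marker, was the gene with the most subunit signal. Its 4 probes (3 on Rik1 replicate 2), which match the genome once, averaged 3.19 for H3K9me3, 1.06 for Clr4, 1.29 for Raf2, 0.58 for Cul4 and 1.72 and 2.33 for Rik1. Within 2 kb on either side H3K9me3 averaged 0.20. The malic enzyme gene mae2 (III 275261 to 277262) had H3K9me3 at 3.46, Clr4 at 1.55 and Cul4 at 0.63, with Rik1 at -0.45 and 1.95. All 6 mae2 probes shared at least 50 of 60 bases with sequence at the ends of chromosome I or II, as did 3 of 4 probes of SPAC977.14c (H3K9me3 2.28, Clr4 0.82) and 2 of 6 probes of mae1 (H3K9me3 1.23, Clr4 0.77). For mae1 and new20 (H3K9me3 1.11) the mark was 0.31 and -0.12 over probes at single-copy input level.

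**Figure D4:**
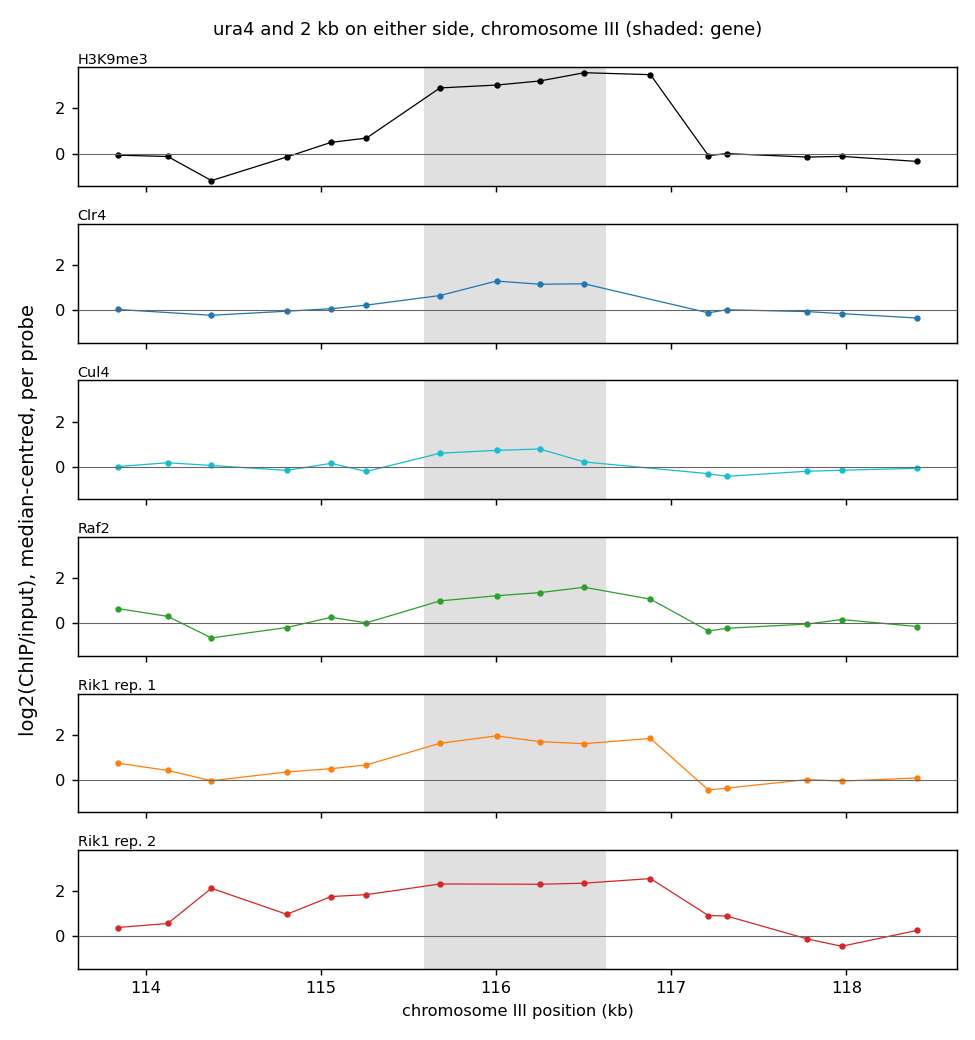
Log2 ratio of ChIP over input per probe on the 6 arrays over ura4 and 2 kb on either side, in kb of chromosome III, with the gene shaded. H3K9me3 reaches 3.58 in the gene and is -0.09 at the probe starting at 117212.

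Single-subunit excesses outside the domains were ranked without regard to a threshold. For Cul4, whose threshold of 1.33 none of them reached, the leading genes were ste4, a pheromone signalling gene, at 0.90 with Clr4 at 0.97, SPCC1235.01, uncertain because its input level was above single copy, at 0.87 and tps1, a trehalose-6-phosphate synthase gene, at 0.79, with H3K9me3 between -0.24 and 0.09. For Raf2, SPBC23G7.10c (II 2118146 to 2119478) stood at 1.09, above the array's threshold of 1.05, with the other arrays between -0.20 and 0.15. For Rik1 the largest excesses were at the mitochondrial genes rnl, cob and cob-I1, which were below 0 on every array except Rik1 replicate 2 and below 0 there too after loess. The tagged genes clr4, rik1, cul4 and raf2 lay between -0.25 and 0.44 on all arrays, which does not bear on the tags.

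The last comparison took gene lists fixed beforehand. None of the 7 Mmi1-target meiotic genes, which are silenced during growth through RNA elimination, passed the enrichment threshold on any array, and their H3K9me3 values ran from -0.12 (mei4) to 0.21 (ssm4), with mcp7 at 0.16, spo5 at 0.06, num1 at 0.04, rec8 at 0.03 and crs1 at -0.06. None of the 11 other meiotic genes or the 18 heterochromatin machinery genes (17 measured for Raf2) passed, with H3K9me3 medians of 0.05 and 0.06. The median of 22 highly transcribed genes was -0.21 for H3K9me3 (percentile 0 of random lists), -0.47 (percentile 0) and -0.16 for Rik1, and -0.00 for Clr4. It was slightly above 0 for Cul4 (0.11 over 21 genes, percentile 99.1) and Raf2 (0.13, percentile 99.8, and -0.01 in the authors' deposited table). Of the telomere-linked helicases only tlh1 had placed probes, with Clr4 at 1.82, Cul4 at 0.77 and Rik1 at 0.13 and 2.92. The mating-type cassette genes mat1-Mc and mat3-Mc, which share probes, had median H3K9me3 of 2.62 and Cul4 of 0.57, with Rik1 at -0.08 and 1.49, and Raf2 was measured at mat3-Mc alone (1.60). For 16 of 171 tRNA genes the medians were 0.35 and 0.24 for Rik1 and 0.06 for H3K9me3, and for 14 of them 0.35 for Raf2, the Rik1 replicate 2 value being -0.13 over probes at single-copy input level.

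Repeated elements separated Rik1 replicate 2 from the other arrays. The 10 measured Tf2 retrotransposons had a median of 1.74 on Rik1 replicate 2 (0.21 after loess) and 0.00 on replicate 1. Their H3K9me3 median was -1.09 and their Raf2 median -0.85, which became 0.31 and 0.39 in the authors' deposited table, so neither has a settled direction. The 24 measured wtf genes, meiotic drivers and their relatives, had 1.33 on Rik1 replicate 2 (0.11 after loess, 0.38 at single-copy input level), with 15 above the array's threshold. They had 0.10 on replicate 1 and -0.36 for H3K9me3 (0.13 in the authors' deposited table). The 23 measured mitochondrial genes had 1.16 on Rik1 replicate 2 (-0.90 after loess), -1.61 on replicate 1 and -2.41 for H3K9me3, and the other arrays, with 13 (Raf2) to 21 (Clr4) of them, lay between -2.38 and -1.70. The input channel differed too: Tf2 probes read 0.76 above the array median in the input of Rik1 replicate 2 and 3.44 to 3.93 on the other arrays, and mitochondrial probes read 1.43 against 4.62 to 4.95.

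**Figure D5:**
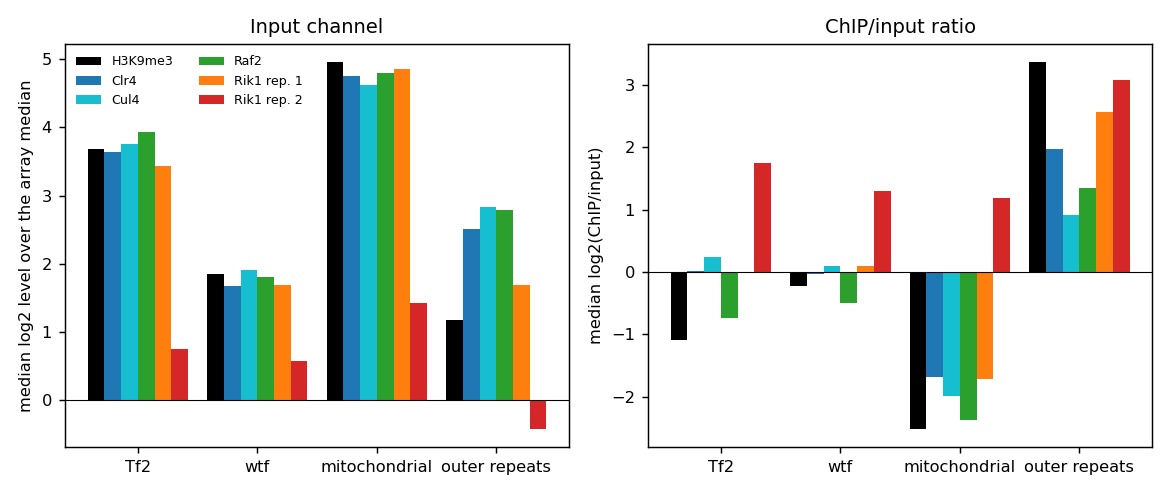
Median log2 level of the input channel over the array median (left) and median log2 ratio of ChIP over input (right) for probes of Tf2 elements, wtf genes, mitochondrial DNA and centromeric outer repeats on the 6 arrays. In the input of Rik1 replicate 2, Tf2 probes read 0.76 and outer-repeat probes -0.41, lower than on the other 5 arrays.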

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

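Of the tests in this part only the scanner ceiling test was written before its result was seen; all others were chosen afterwards. Probes of subtelomeric clones that have no match in the assembly carried a signal that no domain could include, which is why they were set apart. Over these probes H3K9me3 averaged 2.96 (61 probes, SD 0.86), Clr4 1.54 (57 probes, SD 0.39), Raf2 2.19 (50 probes, SD 0.53) and Rik1 replicate 2 3.33 (57 probes, SD 0.70), all above the thresholds of their arrays. Cul4 at 1.00 and Rik1 replicate 1 at 0.99 stayed below theirs. The difference between these probes and the placed probes was not tested.

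The Rik1 arrays differed at Tf2, wtf and mitochondrial DNA, where replicate 2 was above replicate 1. A scanner ceiling is argued against, because 0 percent of Tf2 probes read above 90 percent of the highest input signal and their median was 30.0 percent of it. Compression of multi-copy signal in the input of replicate 2 is consistent with the channel levels: its ChIP channel at Tf2 was not raised but differed from the mean of the other 5 arrays by -1.47, and its input by -2.88. At single-copy mat probes compression cannot be the whole cause, since replicate 2 minus replicate 1 was still 1.24 (36 probes, SD 0.58). Deletion of any of the 18 listed machinery genes in the culture of replicate 1 is argued against as well, their lowest input difference being -0.20. Other genes and smaller mutations were not covered by this test. The input of replicate 1 had lost set7 (-2.68), a gene singled out after its values were seen. The reason for the gap at the mat locus therefore stays open.

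Clr4 and Raf2 lay past the H3K9me3 edge at the right end of chromosome I, with a mean of 0.71 from 35 to 50 kb. Unspecific binding of the tag antibodies is argued against by the arrays that share those tags, Cul4 and Rik1 replicate 1, whose mean there was -0.0610. Rik1 replicate 2, of the same Myc tag as Raf2, was at 0.14 there. A trend with probe GC content is argued against by the corrected mean of 0.70, and dye normalisation by the scanner software by the mean of 0.80 in the authors' deposited table. A hypothesis left open is that Clr4 and Raf2 might occupy this stretch with little H3K9me3, which single arrays cannot settle.

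H3K9me3 and the subunits marked ura4 on chromosome III. Spreading from the neighbouring sequence is argued against by the mean of 0.20 (SD 1.13) within 2 kb, against 3.19 in the gene, and cross-hybridization to another place in the assembly by 0 of 4 ura4 probes having a near match. A copy of ura4 elsewhere, inside heterochromatin, might carry the signal, and its DNA would be read by the same probes. The ura4 input on Rik1 replicate 1 lay at percentile 99.9 of genes, 0.75 above the other older arrays, and that on the Clr4 array at percentile 0.244, with a difference of -0.49. The extra signal on Rik1 replicate 1 cannot be told apart from a ura4 marker at another locus, since the input of the same array had lost set7 (-2.68), a gene singled out after its values were seen. That array is part of the mean the Clr4 array was set against. A copy shared by all strains would not show in such differences. The ura4 input was 0.40 to 1.18 on the older arrays against -0.65 to -0.20 within 2 kb. On Rik1 replicate 2 both were -0.35. Whether this reflects copy number was not tested.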

How the results depend on the processing

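Alternatives with probes at single-copy input level or with outlier spots kept, those with probes that match once for enriched bins, domains and Rik1 bins, those of the correlation between the Rik1 arrays, those of class levels by probe filter, and those of the gene lists by loess, mode, the authors' deposited table or GC content, were chosen after seeing the data; all others were fixed beforehand. Counts were held to 1.5 times their value, and log2 values and shares to 1.5 times or a small margin (0.1 for domain contrasts, 0.2 for gene lists, 0.3 for parts and named genes, 10 percentage points for shares), except that Rik1 contrasts were held to the SD between its arrays. That SD, 1.05, was wider than the replicate 1 contrast of 0.45, so a fall of this contrast to near 0 would still count as kept. The domain count kept under 10 of 14 alternatives, Rik1 bins under 10 of 16, counts of enriched bins under 48 of 84, and the domain contrast of the subunits under 70 of 80, always above 0, with 0.0301 for Cul4 as the lowest. Correlations kept within 0.15 under 105 of 120 for subunits with H3K9me3 and 24 of 28 between the Rik1 arrays, class levels under 57 of 72, parts of domains under 175 of 185 and gene lists under 426 of 456. A genome-wide correlation cannot change under centring on the mode or fixed thresholds, so such alternatives could only count as kept. Of 2502 values of named genes 2376 kept, 3 reversed and the remainder moved. No paired analysis was possible because no groups of samples are compared and only Rik1 has 2 arrays. Input signal over background was between 3.84 and 6.34 on the 5 older arrays and 435 on Rik1 replicate 2, and whether this limits faint binding was not tested. The cause of the changes below was not tested, except that the probe filters leave fewer probes in repeats and other bin sizes change the number of bins. Domains, and thresholds that were not fixed, were set anew under each alternative, except that class levels by probe filter used the main domains.

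H3K9me3-enriched bins numbered 514 in the authors' deposited table, 116 without saturated probes, 108 with 2 kb bins, 417 with 500 bp bins, 368 at a fixed 1.5-fold threshold and 96 with probes that match once. For Clr4 there were 77 with 2 kb bins, 282 with 500 bp bins, 52 with probes that match once and 43 at single-copy input level. For Cul4 there were 0 after normexp, 0 after loess, 541 centred on the mode, 24 with 500 bp bins, 197 at 1.5-fold, 29 at 2-fold, 155 with probes that match once and 48 at single-copy input level. For Raf2 there were 3 after loess, 237 in the deposited table, 42 with 2 kb bins, 161 with 500 bp bins, 182 at 1.5-fold, 40 with outlier spots kept, 44 with probes that match once and 50 at single-copy input level. For Rik1 replicate 1 there were 46 with 2 kb bins, 248 with 500 bp bins, 603 at 1.5-fold, 25 with probes that match once and 22 at single-copy input level. For Rik1 replicate 2 there were 1074 after normexp, 527 with 500 bp bins, 496 at 1.5-fold, 66 with probes that match once and 24 at single-copy input level.

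There were 26 H3K9me3 domains in the deposited table, 24 with 500 bp bins and 8 at single-copy input level, of which 7, 2 and 4 lay away from the known classes, and 5 with probes that match once. The thresholds were 0.5, 1.58, 0.52 and 0.94 in that order, against 1.51 in the main setting. Rik1 was above input in 76 bins centred on the mode, 47 with 2 kb bins, 22 at single-copy input level and 38 with probes that match once. Without replicate 1, the enriched bins of the other array numbered 272, and without replicate 2 they numbered 84, both called by the array's own threshold and not by limma.

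The domain contrast of Clr4 was 0.84 in the deposited table, 0.83 without saturated probes and 0.83 at single-copy input level. That of Cul4 was 0.22 after loess, 0.15 in the deposited table, 0.0729 without saturated probes, 0.14 with probes that match once and 0.0301 at single-copy input level. That of Raf2 was 0.83 after loess, and that of Rik1 replicate 2 was 0.73 at single-copy input level.

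Correlations with H3K9me3 over the genome became 0.50 (probes that match once) and 0.48 (single-copy input level) for Clr4, 0.43 (single-copy input level) for Raf2, and 0.32 (without saturated probes), 0.19 (probes that match once) and 0.21 (single-copy input level) for Rik1 replicate 2. Inside domains they became 0.60 (loess) and 0.22 (probes that match once) for Clr4, 0.51 (single-copy input level) for Cul4, 0.32 (probes that match once) for Raf2, 0.30 (loess), 0.29 (probes that match once) and 0.16 (single-copy input level) for Rik1 replicate 1, and 0.57 (loess) and 0.89 (deposited table) for Rik1 replicate 2. Between the Rik1 arrays the correlation was 0.45 (loess), 0.00940 (probes that match once) and 0.00884 (single-copy input level) over the genome, and 0.12 (single-copy input level) inside domains.

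At chromosome ends Clr4 was 89.5 percent of its centromere mean in the deposited table and Cul4 was -7.90 percent after normexp. With probes that match once, in the main domains, the mat locus was 183 percent for Clr4 and 53.6 percent for Rik1 replicate 1, and chromosome ends were 156 percent for Clr4, 34.3 percent for Cul4, 148 percent for Raf2, 60.9 percent for Rik1 replicate 1 and 101 percent for Rik1 replicate 2. At single-copy input level the mat locus was 195 percent for Clr4, 159 percent for Cul4 and 212 percent for Raf2, and chromosome ends were 164 percent for Clr4, 191 percent for Raf2 and 43.1 percent for Rik1 replicate 1. In the outer repeats, probes that match once and probes at single-copy input level gave 0.94 and 0.82 for Clr4, 0.47 and 0.40 for Cul4 and 1.205 and 0.98 for Rik1 replicate 1. At single-copy input level Rik1 replicate 2 was 1.88 there and -0.53 in the central domain. With the filter for probes that match once, Rik1 replicate 1 was 1.56 in cenH, from 1 probe without a match in the assembly. It was -0.64 in the terminal 10 kb on the left of chromosome I, also from 1 probe.

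Gene lists changed as follows. After normexp the mating-type cassettes were 2.46 on Rik1 replicate 2, Tf2 elements -0.26 for H3K9me3, -0.0946 for Cul4 and -0.32 for Raf2, wtf genes -0.18 for Cul4, and mitochondrial genes -1.13 for H3K9me3 and 0.61 on Rik1 replicate 2. At single-copy input level wtf genes were -0.0828 for H3K9me3, -0.0360 for Raf2 and 0.38 on Rik1 replicate 2, and tRNA genes -0.13 on Rik1 replicate 2. After loess tlh1 was 0.28 for Cul4 and 0.95 for Raf2, and the cassettes were 0.27 for Cul4. Tf2 elements were then -0.22 for Cul4, -1.51 for Raf2 and 0.21 on Rik1 replicate 2, wtf genes -0.27 for Cul4 and 0.11 on Rik1 replicate 2, and mitochondrial genes -0.90 on Rik1 replicate 2. In the deposited table tlh1 was 2.61 for Raf2, Tf2 elements 0.31 for H3K9me3, 0.39 for Clr4, 0.39 for Raf2 and 0.30 on Rik1 replicate 1, wtf genes 0.13 for H3K9me3, 0.16 for Clr4 and 0.17 for Raf2, and mitochondrial genes -0.50 for H3K9me3 and -1.13 for Raf2. The named genes that reversed did so after loess on Rik1 replicate 2: rnl to -0.71, cob to -1.07 and cob-I1 to -0.85.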

Other observations

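The tests behind these values were chosen only after the results were seen. The gene hel2, singled out after its values were seen, carried Rik1 replicate 1 at 3.07 (5 probes, SD 1.37) and between -0.25 and 0.23 on the other arrays. The input of Rik1 replicate 1 was lower over set7 (III 1880992 to 1882309) than on the other older arrays by 2.68 on the log2 scale, the only one of 4927 genes past the limit of -2, the next lowest being -1.05. No gene passed that limit on the other 4 older arrays.

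The mark at ura4 ran from the probe starting at 115679 to the probe starting at 116881, with values from 2.91 to 3.58, and was -0.09 at the probe starting at 117212. Around mae2, which shares sequence with chromosome ends, the 15 probes within 2 kb averaged -0.06 for H3K9me3. At the 2 mat domains, Rik1 replicate 1 was 0.19 in the outer 2 kb and 2.12 more than 5 kb from the domain ends. The latter place held 2 bins, in the stretch that holds cenH. Clr4 was 1.34 and 1.96 in these places. The ends of the array's own stretch are not edges of the mark, since H3K9me3 was 3.34 at its first probe and 2.98 at its last. These distances therefore do not measure a rise from the edge of the mark. Outside the domains the correlation between the Rik1 arrays was 0.00. Of the 146 bins with Rik1 above input, 136 were higher on replicate 2, with means of 1.28 on replicate 1 and 2.38 on replicate 2.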
